A study of Mus musculus with 6 samples.

How the data were processed

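RNA from 6 samples of mouse (C57BL/6) femoral epiphyseal chondrocytes was sequenced on an Ion Proton instrument, per the labels' protocols. Cells grew in DMEM/F12 with 10% FBS and received 0.1% DMSO for 48 h (control), 0.1% DMSO with 10 ng/ml TGF-alpha for 48 h, or 10 µM gefitinib for 30 min followed by gefitinib and TGF-alpha together for 48 h. The series design names PBS rather than DMSO as the control, and it uses the term P2, which is not explained, while the characteristics give postnatal day 1 as the age. Both conflicts were left open. The RNA extraction protocol is not provided in the labels. No gefitinib-only group was analysed here.

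The authors deposited 1 table of read counts per gene, as whole numbers that were not normalized, with 1 column per library, and the replicates were not pooled. The genome build was GRCm38, per the submitters' processing notes. The aligner, the counter, the annotation, whether counting used strand and any filter are not given in the sources used here, so reads of near-identical copies and of overlapping genes could be split in a way that is not known. The table had 44788 genes and other transcripts by symbol, of which 19649 had no count in any library. Entries marked mRNA held 91.3% of the counts and those marked ncRNA 8.03%, and all entries were used. Of the symbols, 32095 were in a RefSeq gene table and 30997 in GENCODE M21, from which positions, GC content and transcript length were taken. Total counts ranged from 12317407 to 16096263, and at the common dispersion edgeR estimated a coefficient of variation of 6.08% between libraries beyond counting noise.

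Counts were analysed in R 4.3.3 with edgeR 4.0.16. Genes were kept by filterByExpr with a minimum count of 10, which left 15362, and library sizes were scaled by the TMM method. A quasi-likelihood model (glmQLFit and glmQLFTest) was fitted to all 6 libraries with group as the only term, which gives 3 residual degrees of freedom, and 11.2 prior degrees of freedom were estimated. Each of the 3 pairs of groups was tested two-sided, p-values were adjusted by the Benjamini-Hochberg method over the tested genes, and a gene was called at an adjusted p under 0.05. CPM values are counts scaled by TMM to a common library size (CPM), given as mean ± SD of 2 libraries. The SE of a log2 fold change was computed as its absolute value divided by the square root of the quasi-likelihood F. Fold changes are given as sizes, with the direction in words. Shares of counts per group were compared by an exact permutation test, and replicate libraries by a chi-square over genes with at least 20 counts.

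The test, its design, the rule for named genes and 31 gene lists, 12 of them markers of cells other than chondrocytes, were fixed before the data were examined. Of the lists 29 had a tested member. They were tested with limma 3.58.1 camera on voom values, with a preset correlation of 0.01, and again with an estimated correlation and with fry, and adjusted over lists within a comparison. With an estimated correlation camera uses only the 3 residual degrees of freedom, which by itself raises its p-values. A call lost in that form therefore does not by itself show correlation between genes. A count described as adjusted over the list alone uses the members' p-values adjusted among themselves. The rule named Egfr and Tgfa, the 6 largest rises and falls among called genes with a mean of at least 5 CPM and no overlap between the libraries compared, and up to 4 called members with the smallest p of each list, or 2 members with the highest mean CPM where none was called. It gave 115, 117 and 97 genes in the 3 comparisons. Only some of them are printed, and these were picked after the values were seen. A few others are not reported here, although they stayed in the tests and in the list counts.

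The fit was tested on simulated data, with counts drawn for the real genes from their shares over all 6 libraries and the real totals, and 200 genes changed by known folds, in 5 runs for each comparison and dispersion, of 15081 to 15127 tested genes. For TGF-alpha against control with each gene's own dispersion, 22.4% of genes changed 1.25-fold, 60% at 1.5-fold, 74% at 2-fold and 94% at 4-fold were recovered, and 12.3% of the calls were false (11.7% and 11.1% in the other comparisons). With dispersions from the trend 5.49% of the calls were false (4.75% and 5.50%). Far more than 200 genes were called in each real comparison, where the adjusted threshold admits larger p-values. These shares therefore do not give the recovery or the false share of the real comparisons. Simulated lists of 25 genes raised 1.3-fold had an unadjusted camera p under 0.05 in 10 of 10 runs for TGF-alpha against control, and unchanged lists in 1 of 10. Their genes were drawn independently, so this check does not cover correlation between genes. The number of genes called in opposite directions in the first 2 comparisons, which share the TGF-alpha libraries, was simulated 20 times without any change. With no gene changed few are called, so that number is not the one expected for lists of the real sizes. For the pair that shares the control libraries, 20 simulations kept the TGF-alpha shares and gave the other groups 1 common share, chosen after the data were seen. Few genes are then called with TGF-alpha plus gefitinib against control, so that overlap is likewise not the one expected for lists of the real sizes. Alternatives were other scaling factors, filters and thresholds, DESeq2 1.42.0, limma-voom, glmTreat against a 1.2-fold change, the replicate number as a block, fits of only the groups compared, and leaving out each library. A fit on mRNA entries only was added after the data were seen.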

Results

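Chondrocytes are the cells that build cartilage, and the 6 libraries came from chondrocytes of the mouse femoral epiphysis, the cartilaginous end of the thigh bone, grown in medium with serum. Transforming growth factor alpha (TGF-alpha) is a ligand of the epidermal growth factor receptor (EGFR), and gefitinib inhibits the kinase of that receptor. There were 3 groups with 2 libraries each: vehicle control, TGF-alpha at 10 ng/ml for 48 h, and the same TGF-alpha treatment with 10 µM gefitinib, which was also given for 30 min before the ligand. The total count per library lay between 12317407 and 16096263, and between 20600 and 21067 genes had at least 1 count in a library. Replicate libraries differed by more than counting noise, with a chi-square per degree of freedom of 3.03 in control, 3.57 with TGF-alpha and 3.83 with TGF-alpha plus gefitinib. Across genes, log CPM correlated at 0.983 to 0.986 between control and TGF-alpha plus gefitinib libraries, and at 0.965 to 0.967 between control and TGF-alpha libraries. Genes are not independent replicates. No source used here says that the replicates were separate cultures or animals, so each p-value measures only the spread between these samples, which may be technical.

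The makeup of the libraries moved with the groups, here shown by 3 genes picked after their values were seen and by the mitochondrial mRNAs. Fn1, which encodes fibronectin, took 4.49% ± 0.00741 of counts in control, 7.23% ± 0.233 with TGF-alpha and 4.30% ± 0.0903 with TGF-alpha plus gefitinib (SD, n = 2 in each). Col2a1, the main collagen of cartilage, took 4.76% ± 0.211, 2.80% ± 0.0506 and 4.27% ± 0.207 of counts in the same order. The 18S ribosomal RNA-like gene Rn18s-rs5 took 1.38% ± 0.0242 of counts in control, 1.03% ± 0.251 with TGF-alpha and 0.721% ± 0.0912 with TGF-alpha plus gefitinib. TGF-alpha 2 stood apart in that gene, at 0.851% against 1.21% in TGF-alpha 1. Mitochondrial mRNAs took 0.788% ± 0.0179, 0.826% ± 0.0206 and 0.965% ± 0.0619. With 2 libraries against 2, an exact two-sided permutation test of such a share cannot go below p = 0.33, so no p-value is given for the shares. Haemoglobin genes had at most 9 counts in any library, and the erythroid and neutrophil marker lists had 0 tested members.

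The first comparison, TGF-alpha against control, concerned the effect of EGFR activation on chondrocyte gene expression, the subject named in the series title. In the fixed lists 21 of 24 cartilage genes fell and 2 rose, whereas 30 of 30 mitosis, 25 of 30 DNA replication and 19 of 22 ERK feedback genes rose and 0 fell. Camera called these 4 lists with a preset correlation and not with an estimated one (adjusted p from 0.0625 to 0.0778). Spp1, which encodes the bone matrix protein osteopontin (chromosome 5, 104435118 to 104441050 in GRCm38), rose 12.8-fold, from 480.1 ± 2.62 to 6161 ± 124 CPM (mean ± SD, n = 2; log2 fold change 3.68 ± 0.04 SE, edgeR adjusted p = 3.12e-16). Matn1, which encodes the cartilage matrix protein matrilin-1, fell from 1342 ± 27.1 to 88.8 ± 13.6 CPM, 15.1-fold (log2 -3.92 ± 0.08, adjusted p = 8.31e-14). In all, 4600 of 15362 tested genes were called, 2446 higher and 2154 lower with TGF-alpha. At least a 2-fold change was seen in 1086 of them, 644 higher and 442 lower, and 2319 genes passed a test against a 1.2-fold change. The libraries of this comparison did not differ in the receptor's own mRNA beyond the test. Egfr (chromosome 11, 16752203 to 16918158 in GRCm38) was at 67.1 ± 2.83 CPM in control and 71.1 ± 1.17 with TGF-alpha (log2 0.08 ± 0.06, adjusted p = 0.369), and endogenous Tgfa at 30.0 ± 0.831 and 28.4 ± 0.882 (adjusted p = 0.557).

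The largest rises among called genes with a mean of at least 5 CPM and no overlap between the libraries compared also included Nptx1, a neuronal pentraxin (chromosome 11, 119538719 to 119547753; 30.1-fold, adjusted p = 1.23e-11), Unc13c, a synaptic vesicle priming protein (20.8-fold, adjusted p = 1.13e-09), and Arc, an immediate early gene (12.3-fold, adjusted p = 1.08e-09). The largest falls included the carbonic anhydrase gene Car3 (19.7-fold), the secreted Wnt modulator Sfrp2 (chromosome 3, 83766321 to 83774316; 13.9-fold, from 332 ± 14.8 to 23.8 ± 2.39 CPM) and the basement membrane gene Fras1 (12.2-fold), with adjusted p of 4.52e-07, 5.82e-14 and 1.19e-09.

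**Figure D1:**
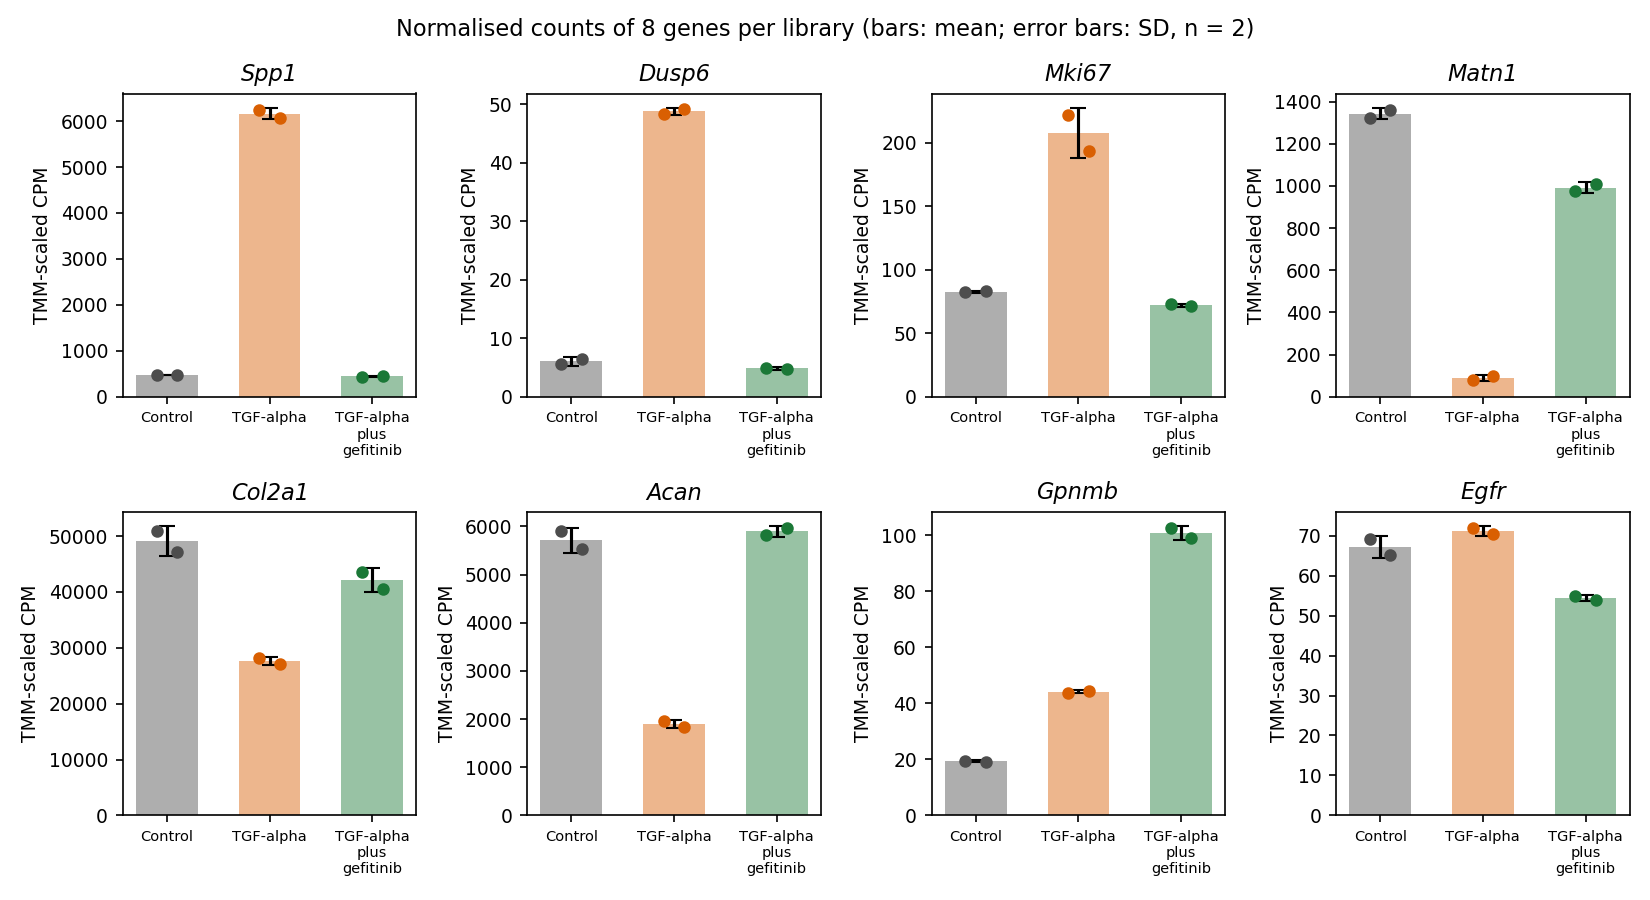
Normalised counts (TMM-scaled CPM, y axes starting at 0) of 8 genes in the control, TGF-alpha and TGF-alpha plus gefitinib groups, where points are libraries, bars are means and error bars are SD of 2 libraries. Spp1 was at 6161 CPM with TGF-alpha against 480.1 in control and 447 with gefitinib added, Matn1 at 88.8 CPM against 1342 and 992, and Gpnmb was highest with gefitinib at 101 CPM.

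Cartilage genes made up the list with the most falls. Of its 24 tested members, 21 fell and 2 rose over all genes tested, and 22 fell and 2 rose when adjusted over the list alone (median log2 -1.23, camera adjusted p = 3.99e-25, and adjusted p = 0.0625 with an estimated correlation). The fibrillar and fibril-associated collagen genes Col9a3 (507 ± 24.8 to 111 ± 1.56 CPM), Col11a2 (2117 ± 166 to 564 ± 1.69) and Col9a1 (2519 ± 79.9 to 832 ± 21.1) fell 4.58-, 3.75- and 3.03-fold. Col2a1, Acan, Sox9, Sox5 and Cytl1 were picked for mention after their values were seen. Col2a1 (chromosome 15, 97975602 to 98004695) fell by 0.83 ± 0.05 on the log2 scale and Acan, which encodes the proteoglycan aggrecan (chromosome 7, 79053483 to 79115099), by 1.59 ± 0.05. Sox9, the master transcription factor of chondrocytes, fell by 0.39 ± 0.05 (adjusted p = 1.31e-05). The members that rose were its partner Sox5 (log2 0.81 ± 0.07) and the secreted protein gene Cytl1 (1.55 ± 0.17).

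Other matrix and skeletal lists moved in both directions. Among 19 tested genes of hypertrophic and mineralizing chondrocytes 7 rose and 5 fell, or 7 and 6 adjusted over the list alone (camera adjusted p = 0.456). Spp1, the pyrophosphate-generating enzyme gene Enpp1 (7.10-fold) and the pyrophosphate transporter gene Ank (3.28-fold) rose, while the alkaline phosphatase gene Alpl fell 7.24-fold (adjusted p = 1.28e-09). Among 18 superficial zone, joint and hyaluronan genes 6 rose and 7 fell (6 and 8 adjusted over the list alone, camera adjusted p = 0.539). The hyaluronan receptor gene Cd44 rose 3.71-fold and the lubricin gene Prg4 4.55-fold, whereas Abi3bp, an extracellular matrix protein gene, fell 3.31-fold and the clusterin gene Clu 3.99-fold. Of 25 matrix-degrading proteases 8 rose and 10 fell, the same counts as when adjusted over the list alone (camera adjusted p = 0.547): the plasminogen activator gene Plat rose 3.16-fold and the aggrecanase-family gene Adamts9 fell 4.50-fold.

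Genes of proliferation and of the ERK pathway rose. All 30 G2/M and mitosis genes rose, also when adjusted over the list alone (median log2 1.27, camera adjusted p = 9.77e-26, and adjusted p = 0.0778 with an estimated correlation). Mki67, a marker of cycling cells, rose from 82.7 ± 0.547 to 208 ± 19.7 CPM, and the topoisomerase gene Top2a from 70.1 ± 4.53 to 165 ± 8.51. Of 30 DNA replication genes 25 rose and 0 fell, with 27 rising when adjusted over the list alone (camera adjusted p = 1.14e-13, and adjusted p = 0.0625 with an estimated correlation). Rrm2 and Rrm1, the subunits of ribonucleotide reductase, rose 2.58- and 2.40-fold. ERK pathway feedback and target genes rose in 19 of 22 cases and fell in 0, the same counts as when adjusted over the list alone (median log2 1.64, camera adjusted p = 5.22e-14, and adjusted p = 0.0625 with an estimated correlation). Dusp6, an ERK phosphatase (chromosome 10, 99263231 to 99267489), rose 8.01-fold from 6.05 ± 0.719 to 48.8 ± 0.590 CPM, the EGFR inhibitor protein gene Errfi1 rose 6.34-fold and the AP-1 factor gene Fosl1 8.58-fold. The EGFR ligand genes Hbegf and Ereg rose 3.22- and 5.97-fold, while 4 members of that list of 9 rose and 1 fell (4 and 2 adjusted over the list alone, camera adjusted p = 0.165).

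Several metabolic and secreted-factor lists also rose. Among cytokines, chemokines and prostaglandin enzymes 10 of 17 rose and 1 fell (11 and 2 adjusted over the list alone, camera adjusted p = 9.52e-06, and adjusted p = 0.0625 with an estimated correlation). Il1rl1, the interleukin-33 receptor gene, rose 10.6-fold and the chemokine gene Cxcl5 3.22-fold. Interferon-stimulated genes rose in 18 of 22 cases and fell in 0 (21 rose adjusted over the list alone, camera adjusted p = 4.25e-08, and adjusted p = 0.304 with an estimated correlation). Their levels were low, with Isg15 at 4.40 ± 0.262 CPM in control and 11.6 ± 2.47 with TGF-alpha. TGF-alpha 2 was above TGF-alpha 1 in 21 of the 22 members, by a factor of 1.29. Cholesterol synthesis and SREBP2 target genes rose in 18 of 24 cases and fell in 0 (20 rose adjusted over the list alone, camera adjusted p = 1.1e-12, and adjusted p = 0.0625 with an estimated correlation). Glycolysis genes rose in 16 of 19 cases and 1 fell, the same counts adjusted over the list alone (camera adjusted p = 7.51e-11, and adjusted p = 0.0625 with an estimated correlation). Pkm, a pyruvate kinase gene, went from 1409.7 ± 37.7 to 2254 ± 43.3 CPM. Of 19 TGF-beta and YAP target genes 12 rose and 4 fell (13 and 4 adjusted over the list alone, camera adjusted p = 0.00016, and adjusted p = 0.19 with an estimated correlation). The ligand gene Tgfb2 fell 2.00-fold. Lysosome and autophagy genes rose in 12 of 27 cases and 2 fell (13 and 2 adjusted over the list alone, camera adjusted p = 0.00475, and adjusted p = 0.19 with an estimated correlation).

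The other lists that fell had medians closer to 0 than the cartilage list. Wnt pathway targets and inhibitors had 9 falls and 1 rise among 21 (10 and 1 adjusted over the list alone, camera adjusted p = 0.00032, and adjusted p = 0.0788 with an estimated correlation). Frzb, a secreted Wnt antagonist, was 3.09-fold lower. In the IGF axis 8 of 16 fell and 3 rose (9 and 4 adjusted over the list alone, camera adjusted p = 0.00113, and adjusted p = 0.0959 with an estimated correlation). Igfbp5, which encodes an IGF-binding protein, went from 3698 ± 45.4 to 1721 ± 34.0 CPM. Integrated stress response and unfolded protein genes fell in 14 of 24 cases and 1 rose (14 and 2 adjusted over the list alone, camera adjusted p = 4.23e-07, and adjusted p = 0.0625 with an estimated correlation). Atf4, which encodes a stress response factor, went from 539.7 ± 1.02 to 322 ± 7.65 CPM. The aryl hydrocarbon receptor and NRF2 list (5 rose and 3 fell of 15, also adjusted over the list alone, camera adjusted p = 0.449) and the p53 list (3 rose and 4 fell of 18, also adjusted over the list alone, camera adjusted p = 0.456) were not called.

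Camera with the preset correlation called 2 marker lists of other cell types in this comparison, those of osteoblasts and endothelium. Fry, which tests a list against no change, also called osteoclast (adjusted p = 0.000472), smooth muscle (0.000628), epithelial (0.00342), tendon (0.0262) and adipocyte markers (0.0387), and 4 further lists that camera did not call: hypertrophic (0.000628), EGFR family (0.00678), aryl hydrocarbon receptor and NRF2 (0.00686) and superficial zone (0.00949). Osteoblast markers fell in 4 of 8 cases and 0 rose (4 fell and 2 rose adjusted over the list alone, camera adjusted p = 0.0268, and adjusted p = 0.19 with an estimated correlation). Smpd3, a sphingomyelinase gene, fell 5.78-fold. Of the tested members, 3 (Alpl, Ibsp, Sp7) are also on the hypertrophic list. Endothelial markers had 2 rises among 3, also adjusted over the list alone (camera adjusted p = 0.0473, and adjusted p = 0.223 with an estimated correlation). They were the transcription factor gene Erg, which is also on the superficial zone list, and Flt1, which was at 1.45 ± 0.0940 CPM with TGF-alpha. That call was lost without Control 1 (adjusted p = 0.0762), Control 2 (0.0554), TGF-alpha 2 (0.0874) or TGF-alpha plus gefitinib 1 (0.0506), and with the replicate number as a block (0.0558). Fibroblast and perichondrial markers had 6 rises and 7 falls of 19 (6 and 8 adjusted over the list alone, camera adjusted p = 0.655), with a median of 0.03, a mean of -0.08 and a test direction of down. Col6a3 rose 2.11-fold and the type I collagen gene Col1a1 fell 2.20-fold. For tendon and ligament markers the median was -0.53, the mean 0.01 and the test direction down (camera adjusted p = 0.817). Camera gave an adjusted p of 0.436 for macrophage, 0.22 for osteoclast, 0.176 for smooth muscle and pericyte, 0.456 for skeletal muscle, 0.404 for adipocyte and 0.456 for epithelial markers, with 3, 2, 1, 0, 0 and 1 rises and 2, 0, 3, 2, 2 and 0 falls in that order. Macrophage markers stayed low, with a sum of 9.05 CPM over the tested markers in control and 16.6 with TGF-alpha.

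The second comparison, TGF-alpha plus gefitinib against TGF-alpha, asked what the EGFR inhibitor changed in ligand-treated cells. With gefitinib 21 of 24 cartilage genes were higher and 2 lower than with TGF-alpha alone, while 30 of 30 mitosis, 26 of 30 DNA replication, 20 of 22 ERK feedback and 14 of 19 glycolysis genes were lower and 1 glycolysis gene was higher. With an estimated correlation camera called none of these 5 lists (adjusted p = 0.0721, 0.0811, 0.0721, 0.0721 and 0.0721). Spp1 fell 13.8-fold to 447 ± 9.35 CPM (log2 -3.78 ± 0.04, adjusted p = 2.31e-16), and Matn1 rose 11.2-fold to 992 ± 24.9 CPM (log2 3.48 ± 0.08, adjusted p = 2.22e-13). Acan rose 3.10-fold, from 1901 ± 83.6 to 5895 ± 105 CPM. In all 5217 of 15362 tested genes were called, 2618 higher and 2599 lower with gefitinib, of which 1210 changed at least 2-fold (524 higher and 686 lower). DESeq2 called 3474, and 2669 passed the test against a 1.2-fold change. Egfr mRNA fell from 71.1 ± 1.17 to 54.4 ± 0.701 CPM (log2 -0.39 ± 0.07, adjusted p = 0.000339) and Tgfa mRNA rose from 28.4 ± 0.882 to 37.6 ± 0.442 (log2 0.40 ± 0.09, adjusted p = 0.00219).

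Nptx1 (36.8-fold), Unc13c (34.4-fold), Arc (23.3-fold), Il1rl1 (15.8-fold) and the glycosyltransferase gene Gcnt4 (15.1-fold) had the largest falls with gefitinib under the same rule, and Car3 (22.6-fold), the synaptotagmin gene Syt1 (14.2-fold), Matn1, the ectodysplasin receptor gene Edar (11.01-fold) and Fras1 (10.3-fold) the largest rises. Cartilage genes rose in 21 of 24 cases and 2 fell, the same counts adjusted over the list alone (median log2 1.08, camera adjusted p = 1.97e-19, and adjusted p = 0.0721 with an estimated correlation). Lect1, the gene of the cartilage glycoprotein chondromodulin, went from 682 ± 30.1 to 2839.6 ± 276 CPM. All 30 mitosis genes fell, also adjusted over the list alone (camera adjusted p = 1.59e-25, and adjusted p = 0.0811 with an estimated correlation). Mki67 fell to 72.2 ± 1.26 CPM. Of 30 DNA replication genes 26 fell and 0 rose (27 fell adjusted over the list alone, camera adjusted p = 1.89e-13, and adjusted p = 0.0721 with an estimated correlation). ERK feedback and target genes fell in 20 of 22 cases and 0 rose (21 fell adjusted over the list alone, camera adjusted p = 5.2e-16, and adjusted p = 0.0721 with an estimated correlation). Dusp6 fell to 4.86 ± 0.201 CPM and the ETS factor gene Etv5 (chromosome 16, 22381309 to 22439719) from 72.9 ± 1.52 to 9.80 ± 0.494.

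Cytokine and prostaglandin genes fell in 10 of 17 cases and 1 rose, the same counts adjusted over the list alone (camera adjusted p = 0.000151, and adjusted p = 0.0811 with an estimated correlation). Ptgs2, the gene of an inducible cyclooxygenase, fell 4.53-fold. Glycolysis genes fell in 14 of 19 cases and 1 rose (15 and 1 adjusted over the list alone, camera adjusted p = 6.96e-08, and adjusted p = 0.0721 with an estimated correlation). Pkm fell to 1348 ± 37.4 CPM. Cholesterol synthesis genes fell in 16 of 24 cases and 0 rose (16 fell and 1 rose adjusted over the list alone, camera adjusted p = 2.24e-05, and adjusted p = 0.0859 with an estimated correlation). Hmgcs1, which encodes an early enzyme of the pathway, fell 1.54-fold. Among TGF-beta and YAP targets 12 fell and 4 rose of 19, also adjusted over the list alone (camera adjusted p = 0.000219, and adjusted p = 0.213 with an estimated correlation). Interferon-stimulated genes fell in 11 of 22 cases and 2 rose (13 and 2 adjusted over the list alone, camera adjusted p = 0.0035, and adjusted p = 0.469 with an estimated correlation). This call was lost without TGF-alpha 2 (adjusted p = 0.0543) and with fry (0.0586).

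Stress response genes rose with gefitinib in 15 of 24 cases and 2 fell (16 and 2 adjusted over the list alone, camera adjusted p = 4.1e-07, and adjusted p = 0.0721 with an estimated correlation). Ddit3, which encodes the stress factor CHOP, went from 102 ± 5.20 to 285 ± 12.9 CPM. Lysosome and autophagy genes rose in 18 of 27 cases and 2 fell, also adjusted over the list alone (camera adjusted p = 2.75e-06, and adjusted p = 0.0811 with an estimated correlation). The sialidase gene Neu1 rose 2.60-fold and the protease gene Ctsd from 1409 ± 38.2 to 2099 ± 45.9 CPM. Of 18 p53 targets 10 rose and 2 fell, also adjusted over the list alone (camera adjusted p = 0.0212, and adjusted p = 0.213 with an estimated correlation). Bax, an apoptosis gene, was 1.498-fold higher. Wnt pathway genes rose in 7 of 21 cases and 4 fell, also adjusted over the list alone (camera adjusted p = 0.04, and adjusted p = 0.213 with an estimated correlation). Sfrp2 went from 23.8 ± 2.39 to 239 ± 1.89 CPM. Osteoblast markers rose in 5 of 8 cases and 2 fell, also adjusted over the list alone (camera adjusted p = 0.0479, and adjusted p = 0.213 with an estimated correlation). Smpd3 rose 3.55-fold. Endothelial markers fell in 2 of 3, also adjusted over the list alone (camera adjusted p = 0.0392, and adjusted p = 0.213 with an estimated correlation). Without TGF-alpha 2 the Wnt and osteoblast calls were lost (adjusted p = 0.0543 for each), as they were with the replicate number as a block (0.0598 for each), and the endothelial call was lost without TGF-alpha 2 (0.0711) or TGF-alpha plus gefitinib 2 (0.130).

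The 14 lists that camera did not call in the second comparison still held genes that changed, and fry called 11 of them, the exceptions being tendon, macrophage and skeletal muscle markers. Over all tested genes 34.0% were called in this comparison, so changed members and a fry call do not set these lists apart. In the hypertrophic list 5 rose and 7 fell of 19 (6 and 7 adjusted over the list alone, camera adjusted p = 0.0934). Enpp1 fell 7.15-fold and the channel gene Panx3 rose 3.995-fold. That list passed without TGF-alpha plus gefitinib 1 (adjusted p = 0.0221) and with no count filter (0.0336). Hbegf fell 2.87-fold. In its list, the EGFR family, 5 fell and 1 rose of 9, also adjusted over the list alone (camera adjusted p = 0.0636, and adjusted p = 0.0336 without TGF-alpha 1). IGF axis genes rose in 7 of 16 cases and 3 fell (8 and 3 adjusted over the list alone, camera adjusted p = 0.0707). The list passed without TGF-alpha plus gefitinib 1 (0.0322) or 2 (0.0485) and with no count filter (0.00912). Of 25 proteases 12 rose and 7 fell (12 and 8 adjusted over the list alone, camera adjusted p = 0.254), and of 18 superficial zone genes 8 rose and 6 fell (9 and 6 adjusted over the list alone, camera adjusted p = 0.465). Fibroblast markers had 6 rises and 10 falls of 19, and the aryl hydrocarbon receptor and NRF2 list 5 rises and 4 falls of 15, both also adjusted over the list alone (camera adjusted p = 0.193 and 0.332). Hmox1, the haem oxygenase gene of the NRF2 list, rose from 89.6 ± 0.607 to 193 ± 1.85 CPM. For tendon markers the median was 0.55 and the test direction up, but the mean was -0.07 (camera adjusted p = 0.972), and for skeletal muscle markers the median was 0.22, the mean -0.04 and the test direction down (0.974). Macrophage, osteoclast, smooth muscle, adipocyte and epithelial markers had camera adjusted p of 0.495, 0.731, 0.465, 0.217 and 0.0862.

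**Figure D2:**
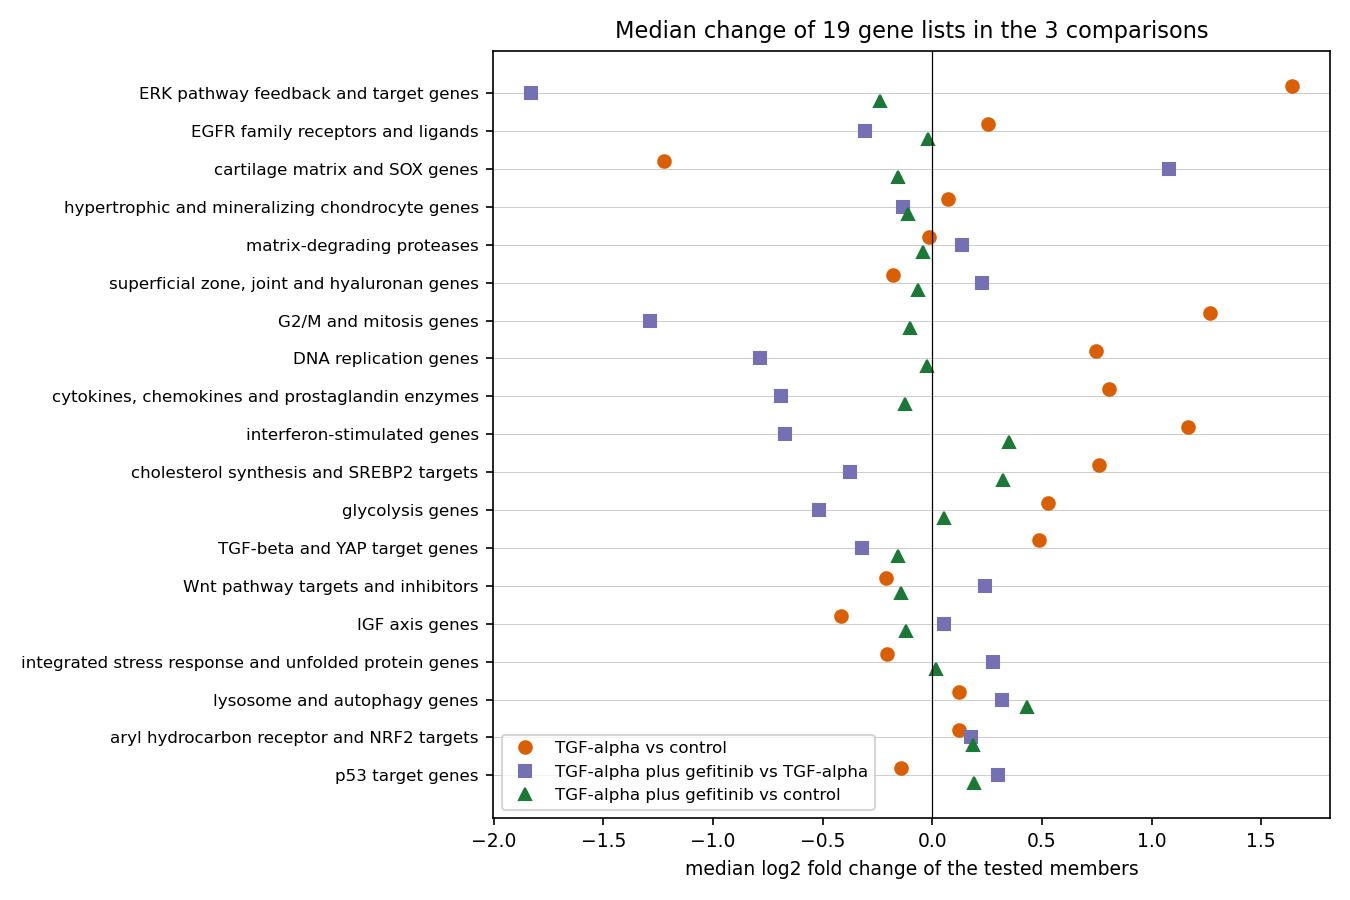
Median log2 fold change of the tested members of 19 gene lists (x axis) in the 3 comparisons, with a circle for TGF-alpha against control, a square for TGF-alpha plus gefitinib against TGF-alpha and a triangle for TGF-alpha plus gefitinib against control. The ERK list lies at 1.64, -1.83 and -0.24 in that order, the cartilage list at -1.23, 1.08 and -0.16, and the lysosome list at 0.12, 0.32 and 0.43.

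Set against each other, the first 2 comparisons moved mostly in opposite directions. Of the 2446 genes that rose with TGF-alpha, such as Spp1, Mki67 and Dusp6, 1816 (74.2%) were called lower when gefitinib was added, 51 higher and 579 not called. Of the 2154 that fell, such as Matn1 and Acan, 1556 (72.2%) were called higher, 22 lower and 576 not called. The sum was 3372 of 4600 (73.3%). In 20 simulated experiments without any change, with the TGF-alpha libraries shared in the same way, it was 0.850 genes on average and 3 at most. With no gene changed few are called in either comparison, so this count is not the number expected for lists of the real sizes. Independent lists of the real sizes would share 414 genes for the risen and 367 for the fallen set, a value that leaves out the shared libraries. Across genes the log2 fold changes of the 2 comparisons correlated at -0.84 with a covariance of -0.355, against -0.51 and -0.0299 in the simulation, a difference in covariance of -0.325. Each comparison uses the same 2 TGF-alpha libraries, which cannot be split into sets of 2, so part of the excess may come from the shared libraries. The count was 1756 when both tests were against a 1.2-fold change and 806 with at least a 2-fold change in both.

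**Figure D3:**
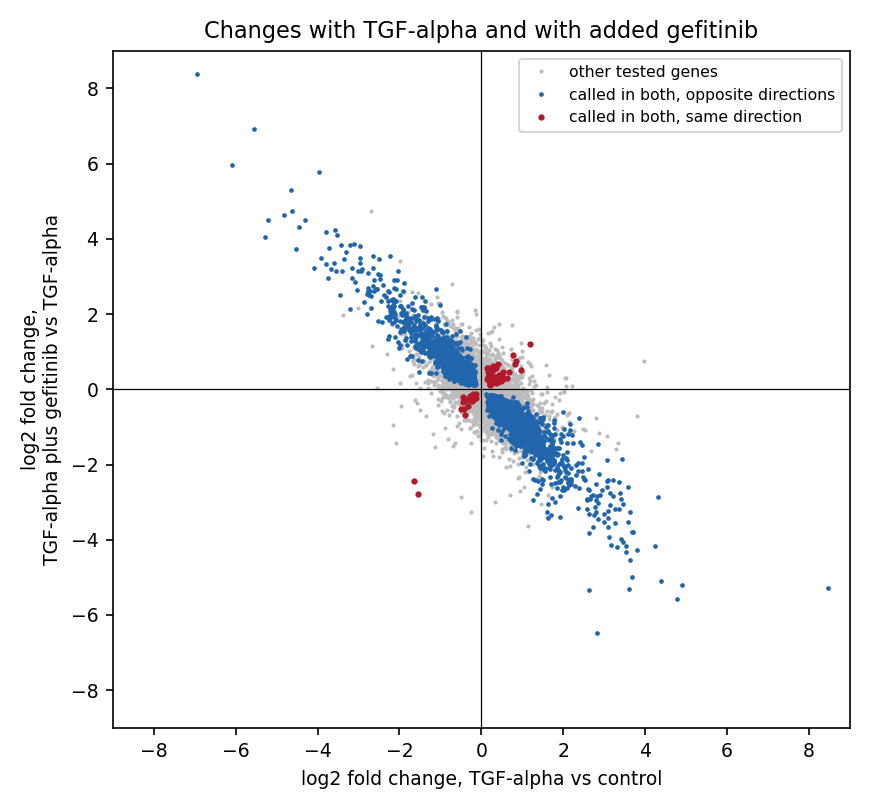
Log2 fold change of each of 15362 tested genes with TGF-alpha against control (x axis) and with TGF-alpha plus gefitinib against TGF-alpha (y axis), where blue points are the 3372 genes called in both in opposite directions and red points the 73 called in both in the same direction. The blue points lie in the upper left and lower right quadrants, and both axes use the same TGF-alpha libraries.

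The third comparison, TGF-alpha plus gefitinib against control, asked what still differed from control cells. Of the lysosome list 22 of 27 genes were higher than in control, and 10 of 19 fibroblast and perichondrial markers and 8 of 24 cartilage genes were lower, with 1 and 2 higher. These lists were not called with an estimated correlation (adjusted p = 0.0776, 0.096 and 0.145). Spp1 was at 447 ± 9.35 CPM against 480.1 ± 2.62 (log2 -0.10 ± 0.04, adjusted p = 0.147). Gpnmb, a transmembrane glycoprotein of lysosomes and melanosomes (chromosome 6, 49036546 to 49070929), rose 5.23-fold, from 19.3 ± 0.334 to 101 ± 2.43 CPM (log2 2.39 ± 0.07, adjusted p = 1.56e-10), and was at 44.1 ± 0.563 with TGF-alpha alone. The metal-binding protein gene Mt1 rose 3.08-fold to 84.4 ± 1.03 CPM and was 144 ± 5.802 with TGF-alpha alone. By the same rule the largest changes were in predicted genes, a 19.8-fold fall of LOC100503055 and a 26.9-fold rise of LOC102634483, which was not called with DESeq2 (adjusted p = 0.0897), limma-voom (0.116) or without Control 1 (0.081) or Control 2 (0.163). Pcsk2, a prohormone convertase gene, fell 3.20-fold, and Etv5 fell from 22.1 ± 0.397 to 9.80 ± 0.494 CPM (adjusted p = 5.6e-06). In all 1463 of 15362 tested genes were called, 809 higher and 654 lower, of which 106 changed at least 2-fold (71 higher and 35 lower). The count was 905 with DESeq2, 709 at an adjusted p threshold of 0.01 and 277 against a 1.2-fold change, and it was 666 without Control 1, 649 without Control 2 and 893 without TGF-alpha plus gefitinib 2.

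Of the 4600 genes called with TGF-alpha, 3768 (81.9%) were not called against control once gefitinib was present. A further 550 were still called in the same direction, 278 higher and 272 lower, and 282 were called on the other side of control. Over all 15362 tested genes only 1463 (9.52%) were called against control with gefitinib, so most genes of any kind were not called. A missing call is also not a test of a return to control. Both comparisons with control use the same 2 control libraries. In 20 simulated experiments where gefitinib undid the whole TGF-alpha change, at most 7 genes were called in the same direction in both (2.85 on average) and at most 3 in opposite directions. In those experiments 5.15 genes on average and 11 at most were called with TGF-alpha plus gefitinib against control, against 1463 here. The simulated overlaps are therefore not the numbers expected for lists of the real sizes, which were not computed for this pair. Among the 644 genes that had risen at least 2-fold with TGF-alpha, the median share of the log2 change left with gefitinib was 1.60% (quartiles -14.2% and 24.8%), and among the 442 that had fallen it was 5.77% (quartiles -10.6% and 23.1%). Matn1, at 992 ± 24.9 CPM against 1342 ± 27.1 in control, was still lower (log2 -0.44 ± 0.06, adjusted p = 0.000552), as was Sfrp2 (log2 -0.48 ± 0.06), whereas Acan was at 5895 ± 105 against 5713 ± 259.6 (adjusted p = 0.61). Matn1, Acan and Spp1 were picked in this comparison after their values were seen. There were 631 genes called in this comparison alone of the pair against control, a difference between comparisons that was not itself tested.

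Egfr mRNA was lower than in control (log2 -0.30 ± 0.07, adjusted p = 0.00926) and Tgfa mRNA higher (log2 0.33 ± 0.09, adjusted p = 0.0281). The Egfr call was lost without Control 1 (log2 -0.26, adjusted p = 0.103). The Tgfa call was lost with DESeq2 (adjusted p = 0.147), without Control 1 (0.0940), Control 2 (0.175), TGF-alpha plus gefitinib 1 (0.0845) or TGF-alpha plus gefitinib 2 (0.122).

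Lysosome and autophagy genes were the list with the most rises in this comparison: 22 of 27 rose and 0 fell, with 23 rising when adjusted over the list alone (median log2 0.43, camera adjusted p = 6.07e-25, and adjusted p = 0.0776 with an estimated correlation). Ctsd went from 1268 ± 23.2 to 2099 ± 45.9 CPM, the cholesterol-carrying protein gene Npc2 from 255 ± 1.04 to 430.5 ± 23.3, and the lysosomal membrane protein gene Lamp1 from 470.3 ± 1.03 to 714 ± 11.8. In the same libraries the share of Rn18s-rs5 was lower (0.721% against 1.38% in control), the tested macrophage markers summed to 10.8 CPM against 9.05 with 0 of 6 called by edgeR, DESeq2 or limma-voom and 2 at an unadjusted edgeR p under 0.05, and the osteoclast markers to 149.7 against 122, of which Ctsk, a cathepsin gene that is also on the protease list, was the single called member, at 98.3 ± 0.485 CPM. Proteases had 4 rises and 2 falls of 25 (4 and 4 adjusted over the list alone; median -0.04, mean 0.02, test direction up, camera adjusted p = 0.959), and the 4 risen members were the cathepsin genes Ctsl, Ctsb and Ctsk and the membrane-type metalloproteinase gene Mmp14. Cholesterol synthesis genes rose in 12 of 24 cases and 0 fell (14 rose adjusted over the list alone, camera adjusted p = 3.18e-10, and adjusted p = 0.096 with an estimated correlation). Insig1, a sterol sensor, rose 2.02-fold. Aryl hydrocarbon receptor and NRF2 targets rose in 3 of 15 cases and 1 fell, also adjusted over the list alone (camera adjusted p = 0.000549, and adjusted p = 0.145 with an estimated correlation). Hmox1 was 1.70-fold higher.

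Of 18 p53 targets 4 rose and 1 fell (7 and 1 adjusted over the list alone, camera adjusted p = 0.00183, and adjusted p = 0.145 with an estimated correlation). Bax rose 1.37-fold. Interferon-stimulated genes rose in 5 of 22 cases and 0 fell, also adjusted over the list alone (camera adjusted p = 0.000275, and adjusted p = 0.472 with an estimated correlation). Fry did not call this list (adjusted p = 0.123). Ifit3 was at 14.8 ± 0.253 CPM against 5.26 ± 0.931. Stress response genes had 6 rises and 1 fall of 24 (7 and 2 adjusted over the list alone, camera adjusted p = 0.167). Ddit3 rose 1.81-fold. Glycolysis genes rose in 4 of 19 cases and 0 fell (4 rose and 1 fell adjusted over the list alone, camera adjusted p = 0.0378, and adjusted p = 0.243 with an estimated correlation). This call was lost with fry (adjusted p = 0.0948) and without Control 2 (0.288) or TGF-alpha plus gefitinib 2 (0.0953).

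Cartilage genes fell in 8 of 24 cases and 2 rose (13 and 2 adjusted over the list alone; median log2 -0.16, camera adjusted p = 2.75e-05, and adjusted p = 0.145 with an estimated correlation). Col9a1 was at 1769 ± 31.3 CPM against 2519 ± 79.9, whereas the matrilin gene Matn3 was higher, at 53.05 ± 4.47 against 31.0 ± 1.17. Hypertrophic genes fell in 5 of 19 cases and 0 rose, also adjusted over the list alone (camera adjusted p = 0.00279, and adjusted p = 0.145 with an estimated correlation). The bone sialoprotein gene Ibsp fell 1.79-fold and the collagenase gene Mmp13 1.28-fold. Fibroblast and perichondrial markers fell in 10 of 19 cases and 1 rose (13 and 2 adjusted over the list alone, camera adjusted p = 1.07e-08, and adjusted p = 0.096 with an estimated correlation). Postn, the periostin gene, fell 1.73-fold and the growth factor receptor gene Pdgfra 1.47-fold. ERK feedback genes fell in 3 of 22 cases and 1 rose, also adjusted over the list alone (camera adjusted p = 0.00206, and adjusted p = 0.243 with an estimated correlation). The member that rose was Ier3, an immediate early gene (log2 0.37 ± 0.06). IGF axis genes fell in 6 of 16 and 1 rose (8 and 1 adjusted over the list alone, camera adjusted p = 0.000275, and adjusted p = 0.145 with an estimated correlation). Wnt genes fell in 5 of 21 and 1 rose (7 and 1 adjusted over the list alone, camera adjusted p = 0.00459, and adjusted p = 0.145 with an estimated correlation). Osteoblast markers fell in 3 of 8 and 1 rose, also adjusted over the list alone (camera adjusted p = 0.0171, and adjusted p = 0.199 with an estimated correlation and 0.0717 with no count filter).

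TGF-beta and YAP targets fell in 7 of 19 cases and 2 rose (7 and 3 adjusted over the list alone, camera adjusted p = 0.0422, and adjusted p = 0.444 with an estimated correlation). Their call was lost with fry (adjusted p = 0.108) and without Control 1 (0.0833) or TGF-alpha plus gefitinib 2 (0.242). Among 9 smooth muscle and pericyte markers 1 fell and 0 rose (2 fell adjusted over the list alone, camera adjusted p = 0.0369, and adjusted p = 0.233 with an estimated correlation). The list's call was lost without Control 2 (adjusted p = 0.0535) or TGF-alpha plus gefitinib 1 (0.0788). Its fallen member, the actin-binding protein gene Tagln (log2 -0.24 ± 0.06, adjusted p = 0.0335), was not called with DESeq2 (adjusted p = 0.0513), with the replicate block (0.0504) or without Control 1 (0.275), Control 2 (0.0541) or TGF-alpha plus gefitinib 1 (0.145). Of the 30 mitosis genes 1 fell and 0 rose (0 adjusted over the list alone, camera adjusted p = 0.0561). That gene, Kif23 (adjusted p = 0.0433), was not called with DESeq2 (adjusted p = 0.153), limma-voom (0.0666) or the replicate block (0.0583), nor without any single library (Control 1 0.103, Control 2 0.222, TGF-alpha 1 0.0621, TGF-alpha 2 0.0634, TGF-alpha plus gefitinib 1 0.071 and 2 0.196). The list passed without Control 1 (adjusted p = 0.0186), TGF-alpha 1 (0.0443) or TGF-alpha 2 (0.0433), with the replicate number as a block (0.0425) and with no count filter (0.0332). Of 30 DNA replication genes 0 passed with edgeR, over all genes or adjusted over the list alone, 0 with DESeq2 or limma-voom, and 4 had an unadjusted edgeR p under 0.05 (camera adjusted p = 0.514), and Mcm2 was at 60.0 ± 2.65 CPM against 61.8 ± 2.34. The cytokine list had 1 rise and 3 falls of 17 (3 and 4 adjusted over the list alone), a median of -0.12, a mean of -0.15 and a test direction of up (camera adjusted p = 0.959). Ptgs2 fell 2.03-fold. Adipocyte markers had a median of -0.09, a mean of 0.04 and a test direction of up (camera adjusted p = 0.514). Plin4, a lipid droplet gene, rose 2.74-fold. Camera adjusted p was 0.514 for the EGFR family, 0.646 for superficial zone, 0.13 for tendon, 0.514 for macrophage, 0.408 for osteoclast, 0.539 for endothelial, 0.206 for skeletal muscle and 0.0621 for epithelial markers. Of the lists that camera did not call here, fry called osteoclast (adjusted p = 0.000516), epithelial (0.00231), stress response (0.00708) and protease genes (0.0405). The epithelial transcription factor gene Trp63 fell 1.72-fold.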

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

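All alternatives here were chosen before the data were examined, except the fit on mRNA entries, which was chosen after the data were seen and called 4674, 5265 and 1732 genes in the 3 comparisons, with 3478 in opposite directions. With TGF-alpha against control, 2319 genes passed glmTreat against a 1.2-fold change and 1086 changed at least 2-fold. With TGF-alpha plus gefitinib against TGF-alpha, 3474 were called by DESeq2, 2669 by glmTreat and 1210 at 2-fold or more. Against control, TGF-alpha plus gefitinib gave 905 with DESeq2, 277 with glmTreat, 709 at an adjusted p under 0.01 and 106 at 2-fold or more. The count in opposite directions was 1756 with glmTreat and 806 at 2-fold or more. All of these use a stricter test or threshold except DESeq2, for which the cause was not tested. Under the other settings with all libraries each of these counts stayed within 1.5 times the reported value. Leaving out each library gave 3297 to 4767, 3703 to 4950 and 649 to 1291 calls in the 3 comparisons and 2484 to 3049 in opposite directions, with fewer samples in each fit and the lone library of a group assumed to vary like the other groups. The balance of higher and lower calls depends on the settings. With upper-quartile factors it turned from 2446 and 2154 to 2244 and 2413 for TGF-alpha against control, and from 809 and 654 to 723 and 784 for TGF-alpha plus gefitinib against control. For gefitinib against TGF-alpha it was nearly even, and it turned from 2618 and 2599 to 2567 and 2640 with DESeq2-style size factors. It also turned under settings that kept TMM, among them the stricter filter (2520 and 2645), limma-voom (2571 and 2593) and the replicate block (2513 and 2529). Upper-quartile factors did not turn it (2707 and 2537).

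Of 29 lists, limma camera called 15 in each comparison with the preset correlation and 0 in each with an estimated correlation, where 10, 9 and 9 had an unadjusted p under 0.05, and fry called 24, 25 and 16. The form with an estimated correlation has only 3 degrees of freedom. For TGF-alpha against control the estimate was 0.232 for the G2/M list and -0.0546 for the cytokine list, under the preset 0.01. Both calls were lost, so correlation between genes alone does not account for the losses. Fry ended 4 of the preset calls: interferon genes with gefitinib against TGF-alpha (adjusted p = 0.0586), and interferon (0.123), glycolysis (0.0948) and TGF-beta and YAP genes (0.108) with gefitinib against control. Test directions that reversed belong to lists that were not called. For tendon markers the adjusted p with no filter was 0.892 for TGF-alpha against control and 0.872 for gefitinib against TGF-alpha, where leaving out each library gave 0.740 to 1.00. Skeletal muscle markers gave 0.703 to 0.949 in that comparison. Against control with gefitinib, cytokines gave 0.788 to 0.987 and proteases 0.665 to 0.987 when each library was left out. The log2 fold change of Erg against control ranged from -0.20 to 0.00866 and that of Egfl7 from -0.64 to 0.62, and neither gene was called. The cause was not tested. Among the named genes, DESeq2 ended 21 calls and leaving out 1 library or another ended 46, with no called gene turning its direction. Named genes without an adjusted p from DESeq2 were not counted, so the 21 may be too low.

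Samples with the same replicate number showed little shared deviation across genes, with correlations of 0.00340, 0.0108 and -0.0228. Whether they were paired by culture, animal or run cannot be told from these values. With the replicate number as a block, 4450, 5042 and 1335 genes were called and 3267 in opposite directions. The block gave list calls of 14, 13 and 16, in which endothelial markers (adjusted p = 0.0558, TGF-alpha against control) and Wnt and osteoblast genes (0.0598 each, gefitinib against TGF-alpha) were lost and the G2/M list (0.0425, TGF-alpha plus gefitinib against control) was gained, and 4 named genes lost their call. It reversed the test direction of cytokines (0.999) and proteases (0.986) against control. In a simulation of TGF-alpha against control at these depths, with 200 genes changed, 60% of those changed 1.5-fold were recovered, so changes can be missed. Far more than 200 genes were called in the real comparison, so this share does not give its recovery.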

Other observations

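All genes in the first 2 paragraphs were picked after their values were seen, and so were the tests below, except those of the Lars2 sequence, the histone genes and GC content, which were written before their results were seen. With TGF-alpha plus gefitinib 496 genes were higher than in both other groups and 349 were lower, of which 315 and 175 were not called for TGF-alpha alone. Enpp2, which encodes the lysophospholipase autotaxin, went from 52.0 CPM in control and 14.0 with TGF-alpha to 99.2 with gefitinib added (log2 0.93 ± 0.07 against control and 2.82 ± 0.08 against TGF-alpha). Gpx3, a secreted glutathione peroxidase, was at 19.6, 9.12 and 58.1 CPM in the same order. Also in the higher set were Plin4, a lipid droplet protein (6.38, 7.42 and 17.5 CPM), the fatty acid binding protein gene Fabp5 (11.2, 7.79 and 22.6) and the acyl-CoA binding protein gene Dbi (104, 98.1 and 192). The folliculin gene Flcn, known for its role in amino acid signalling at lysosomes, was at 21.5, 23.7 and 44.8 CPM.

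Genes lower with gefitinib than in both other groups included Ahr, the aryl hydrocarbon receptor gene, at 59.6 CPM in control, 118 with TGF-alpha and 30.1 with gefitinib (log2 -0.99 ± 0.07 against control, edgeR adjusted p = 7.33e-07). Adam8, a membrane metalloproteinase, was at 8.64, 57.6 and 4.55 CPM, and Dio3, which inactivates thyroid hormone, at 4.79, 14.8 and 1.80. The extracellular matrix gene Smoc1 (171, 206 and 101 CPM) and the joint-forming growth factor gene Gdf6 (25.3, 25.9 and 14.6) fell against control with gefitinib by 0.75 and 0.79 on the log2 scale. Without a gefitinib-only group, an effect of the drug cannot be separated from that of the combination.

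Lysosome and autophagy genes were higher with gefitinib than in both other groups, with 18 of 27 tested members called above each. After a fit on GC content, length and expression level the median log2 change of the list against control was 0.41 (95% bootstrap interval 0.32 to 0.51), against 0.43 before, so these properties do not account for it. Bootstrap intervals here and below resample the genes of a list as if independent. They do not measure the spread between libraries. The summed CPM of all 29 macrophage and osteoclast markers rose by 29.3, less than Ctsk alone (64.3 to 98.3), against a rise of 2185 CPM in the list, or 1.34% of that rise, which argues against those cells as the source. A biological response of the chondrocytes to gefitinib in the presence of TGF-alpha may be a candidate explanation, as a hypothesis found in the same data, and the design has no group to test it.

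Rn18s-rs5 and Lars2 counts were both lower with gefitinib, with Lars2 at 1548, 1181 and 738 CPM, but also in TGF-alpha 2 without gefitinib (Rn18s-rs5 at 8344 CPM against 11956 in TGF-alpha 1, and Lars2 at 955 against 1407). The ratio of Lars2 to Rn18s-rs5 counts varied 1.15-fold over the 6 libraries while Lars2 varied 2.41-fold, so Lars2 counts may follow reads from ribosomal RNA. The longest alignment of a Lars2 transcript to 3 ribosomal transcripts was 15 bases, under the bound set beforehand, but no 28S transcript was among those searched (the longest had 3329 bases, a reservation added after the result was seen), so shared sequence stays open. Replication-dependent histone genes, whose mRNAs mostly lack a poly(A) tail, had a median log2 change of 0.0773 (95% bootstrap interval -0.19 to 0.52, n = 10) against control, which met the bound set beforehand against a loss of RNA without such a tail. That bound was too narrow, since Rn7s1, Rn7s2 and Rn7sk, short RNAs also without the tail, had a median log2 change of -3.53, with 46 and 41 Rn7sk counts in control, 29 and 10 in TGF-alpha 1 and 2, and 7 and 6 with gefitinib, so such a loss stays open.

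Interferon-stimulated genes were higher in TGF-alpha replicate 2 than in replicate 1, in 21 of 22 tested members, by a factor of 1.29. The median log2 change against control was 0.87 (95% bootstrap interval 0.45 to 1.05) in replicate 1 alone and 1.11 in replicate 2, so the rise may not rest on replicate 2 alone, although with 1 library in each the question stays open. No biological explanation was tested.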
